A study of Homo sapiens with 8 samples.

How the data were processed

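The data are 8 dual-colour arrays, 4 of cells in normal and 4 of cells in high methionine, each a separate biological replicate per the labels. RNA was split with an m6A antibody, calibration spike-in RNA was added in equal amounts to the bound (IP) and unbound (Sup) fractions, and the fractions were amplified and labelled with Cy5 and Cy3, per the labels' protocols; no dyes were swapped. The arrays carry 62976 features, among them 60541 distinct transcript probes.

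The deposited values are spot intensities from Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. Per the file headers, the deposited processed intensity of each channel was background-subtracted, detrended and dye-normalized within the array by a linear and a Lowess step, and the arrays were not scaled to each other. The files also hold background-subtracted intensities before dye normalization, median spot and background intensities, and the log10 ratio of red to green made by Feature Extraction, per the file headers; the log10 ratio recomputed from the processed intensities differed from the deposited one by at most 0.0933. Any further step by the authors, such as array scaling or calling of methylated transcripts, is not given in the sources used here.

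Spots with an outlier mark were left out and the remaining spots of a probe were averaged on the log scale. Dye normalization within the array removes a shift common to all transcripts, so the ratio measures a transcript relative to the others on its array. The m6A ratio was log2 of IP over Sup, centred on each array's median over the probes tested. The m6A quantity was log2 of IP, and abundance log2 of IP plus Sup, each minus the array's 75th percentile. A probe was tested if it stood well above background on at least 4 of the 8 arrays, in both channels for the ratio, in IP for the quantity and in either channel for abundance. High was compared with normal methionine in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. Blocks were fixed terms in the linear model. The package statmod 1.5.0 was loaded too, and files were read with pandas 2.3.3 and NumPy 2.4.6. Single values were compared by exact two-sided permutation over 70 relabellings, whose smallest p is 0.0286. The p-values measure the spread between cultures of a single cell line.

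On simulated data built on the 41322 probes of the m6A ratio, changes of 1 and 1.5 log2 units were recovered for 72% and 94% of 50 probes each, and of 0.585 units for 2%. For abundance (47551 probes) the shares were 88%, 96% and 12%, and for the m6A quantity (45102 probes) 56%, 96% and 6%. Only 50 probes per size were changed, with independent normal errors and no slide effect. In the data many more were called, 8576 for abundance, so these shares need not hold there.

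Of the transcript probes 50 carry a RefSeq accession, and all 50 matched a symbol in the RefSeq table of assembly GRCh38.p14, which was used for names only; no coordinates are given, because the header of the array design names another build. Each of these probes was spotted 10 times. The comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for the ratio and abundance, up to 10 genes per direction with the largest difference among those past the threshold, without overlap between groups and above background on at least 6 arrays, or the 5 with the lowest p where none passed; it also named PPARG, 3 m6A writers, 2 erasers and 2 methionine adenosyltransferase genes, which were not analysed here. Some named genes, among them the one with the largest fall in abundance, are counted but not reported here by name. Members of described groups were named too, and the examples given for a group were chosen after their values were seen; the m6A quantity had no rule, and its examples were chosen after their values were seen. The 30 gene lists fixed beforehand could not be tested, since none had 5 tested genes and only 3 had a named member (CCNA2 for the cell cycle, SPP1 for immunosuppressive macrophages, ZAP70 for T and NK cells). Groups of the 50 names (replication and repair, mitosis and kinetochore, transcription and translation, immune and blood cells, matrix and adhesion, lymphocyte markers, liver and epithelial markers, and the rest) were drawn up once the names were known and before any value was compared. Groups with at least 5 tested genes were tested with camera (preset correlation 0.01, and again with an estimated one) and fry.

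The file headers give 2 scans, each taken here as a slide: slide 1 holds 3 normal and 3 high arrays, and slide 2 normal replicate 4 and high replicate 1. No array position occurs in both scans, so a single slide scanned in parts cannot be excluded, and slide here stands for scan. All normal arrays lie in one row of array positions and all high arrays in the other. Median processed IP intensity ranged from 194.3 to 298.6 over the arrays, and no spot of a transcript probe was saturated. Probes whose IDs begin with ASSPINKEIN (102, of which 41 are above background in both channels on all arrays) were taken as the calibration spike-in; the files do not state this.

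Alternatives were normexp background correction (offset 50) with and without within-array loess, scaling by spike-in probes, scale or quantile normalization, other filters on dim probes, the replicate number or the slide as a block, array weights, a trended and robust prior, an unadjusted p under 0.05 with a 1.5-fold change, the percent of signal in the IP channel, the Sup channel alone, the mean of both log2 signals, and each array left out in turn. The files hold no mean spot signals, so normexp used medians. Slide 1 alone, the probes used for spike-in scaling (the 41 bright ones), the medians in normexp and the alternatives for counts of named genes were settled after the files were seen.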

Results

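THP-1 is a human monocytic leukaemia cell line that becomes adherent and macrophage-like when treated with the phorbol ester PMA. The study asked whether raised methionine alters N6-methyladenosine (m6A), a methyl mark on RNA, in such cells, and its title names PPARG as the transcript of interest. Cells from 4 cultures in ordinary methionine and 4 cultures kept for 48 h in 0.8 mM methionine were compared, with 1 array per culture. On each array the RNA bound by an m6A antibody (IP) carried Cy5 and the unbound remainder (Sup) carried Cy3. The ratio of IP to Sup was taken as the m6A level of a transcript and their sum as its abundance. The channels were dye-normalized within the array and, in the main comparisons, not calibrated on the spike-in RNA. The ratio is therefore relative to other transcripts, and the sum may weight the fractions unequally. Between 71.8% and 75.2% of transcript spots stood well above background in the IP channel, and between 69.3% and 75.6% in the Sup channel. The number of arrays, 4 per group, limited the precision of every value.

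The files pair 50 probes with a RefSeq accession, and these 50 genes, mostly of DNA replication, mitosis, chromatin and immune cells, are the ones described by name. The other 60491 transcript probes carry no gene name in the files. PPARG, the m6A writers METTL3, METTL14 and WTAP, the erasers FTO and ALKBH5, and the methionine adenosyltransferase genes MAT2A and MAT2B were therefore not analysed here.

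The first comparison asked which transcripts differed in m6A level. The m6A ratio of KIF20A, a mitotic kinesin, fell by 1.21 on the log2 scale in high methionine (SE 0.18, limma adjusted p = 0.0145, n = 4 per group), from 70.5% ± 2.26 of its signal in the IP channel to 52.1% ± 5.87 (SD). PRIM1, the catalytic subunit of DNA primase, fell by 1.00 (SE 0.17, adjusted p = 0.0215), from 50.4% ± 4.47 to 34.7% ± 2.95 in the IP channel. MOCOS, which sulfurates the molybdenum cofactor of xanthine dehydrogenase and aldehyde oxidase, fell by 0.99 (SE 0.16, adjusted p = 0.0163), from 38.8% ± 4.37 to 25.1% ± 0.597. For all 3 genes the 4 high-methionine arrays lay below the 4 control arrays; the rule for named genes required that the groups not overlap. No named gene had a higher ratio past the threshold of limma, the only tool run here, among the 44 tested. The 5 with the lowest p among those with a higher estimate, none of which passed, were CCNA2 (0.25, adjusted p = 0.485), PLA2G4A (0.16, adjusted p = 0.636), DSCC1 (0.16, adjusted p = 0.776), CHAF1B (0.09, adjusted p = 0.879) and SERPIND1 (0.09, adjusted p = 0.884).

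**Figure D1:**
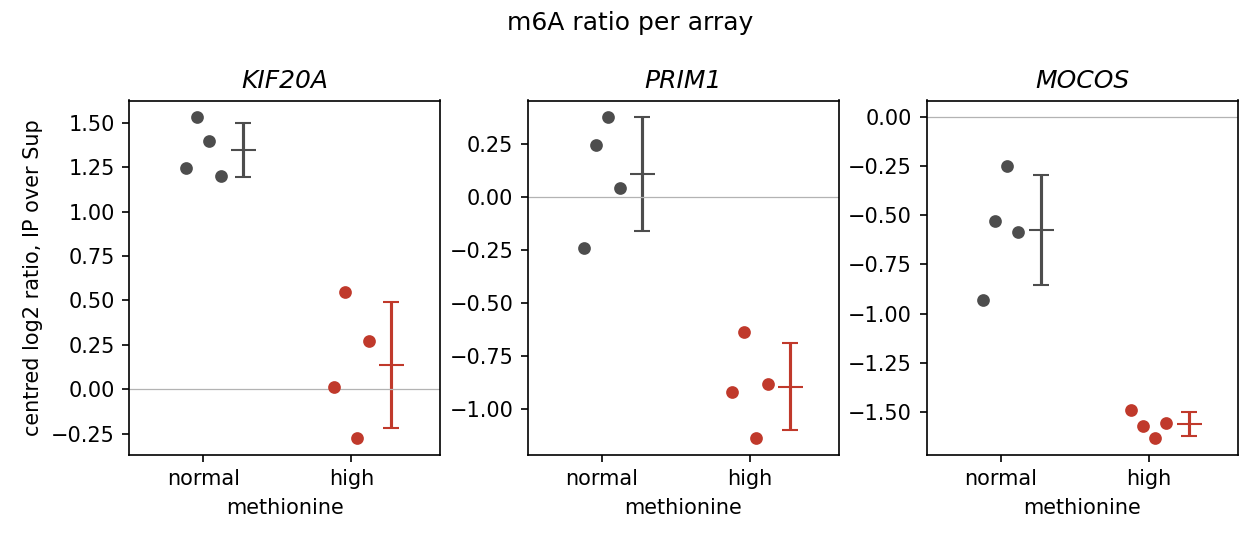
Median-centred log2 ratio of IP to Sup for KIF20A, PRIM1 and MOCOS on each array (points), with the group mean and SD beside them, for 4 arrays in normal and 4 in high methionine; each panel has its own vertical scale. KIF20A averaged 1.34 in normal and 0.14 in high methionine, PRIM1 0.11 and -0.90, and MOCOS -0.57 and -1.56.

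Estimates below 0 were found for 36 of the 44 named genes tested for the m6A ratio, and their median difference was -0.22. Among 9 genes of transcription, ribosome assembly and translation the median was -0.25 and none passed singly; examples were BAZ1A, a chromatin remodelling subunit (-0.44, adjusted p = 0.132), DNTTIP2, a nucleolar protein (-0.37, adjusted p = 0.148), and EIF5B, a translation initiation factor (-0.24, adjusted p = 0.477). PRIM1 was the 1 of 12 replication and repair genes that fell, and the group's median was -0.25. KIF20A was the 1 of 6 mitosis and kinetochore genes that fell, with a group median of -0.45. Set against all other probes, these 3 groups had lower ratios by camera (adjusted p = 0.0119, 0.0147 and 0.0147). None of the 3 calls held with an estimated correlation between genes (adjusted p = 0.363, 0.456 and 0.456). In fry, which tests whether the members move one way on balance, the adjusted p was 0.0419 for the transcription and translation group, 0.164 for replication and repair and 0.0820 for mitosis. The camera calls for replication and repair and for mitosis were lost without normal-methionine replicate 4 (adjusted p = 0.205 each, with a median of -0.14 for the former) and on slide 1 alone (0.0638 and 0.0722, with a median of -0.29 for the latter), the mitosis call also with dim probes kept (0.127), and all 3 were lost without high-methionine replicate 4 (adjusted p from 0.0503 to 0.0717). After normexp the median was -0.22 for mitosis and -0.42 for transcription and translation. The 7 immune and blood cell genes tested, which include LMO2, a haematopoietic transcriptional regulator (-0.14, adjusted p = 0.747), did not pass camera (adjusted p = 0.222), nor did the 6 remaining genes, which include MOCOS (adjusted p = 0.0797). Those 6 passed camera in 5 of 20 alternatives, among them normexp (adjusted p = 0.00712) and normexp with loess (0.00333). Within the named genes alone no group differed from the rest (adjusted p between 0.743 and 0.991). None of the 4 matrix and adhesion genes, the 3 lymphocyte markers or the 1 liver and epithelial marker tested had a changed ratio; these groups were too small for a group test.

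Over all 41322 probes tested, 757 had a changed m6A ratio (limma, Benjamini-Hochberg adjusted), of which 214 rose and 543 fell. At an unadjusted p under 0.05 there were 6916. The 4 values of each group did not overlap for 4592 probes, 11.1% of those tested, where chance gives 2.86%. Of the probes without a name, ASHG19AP1B11023723011 had the largest rise (2.97, SE 0.27, adjusted p = 0.00231) and ASHG19AP1B12349970511 the largest fall (-3.37, SE 0.53, adjusted p = 0.0164) under the rule for named genes. With the slide as a block 1955 probes changed and 5 named genes fell, and on slide 1 alone, with 3 arrays per group, 217 probes changed and no named gene passed (KIF20A -1.21, PRIM1 -1.02, MOCOS -1.02 there). Slide 2 held 1 array per group and allowed no test; of the 237 probes called on slide 1 among those with a value on every array, 230 (97.0%) differed in the same direction on slide 2, against 65.7% of all probes. The count dropped to 160 without normal-methionine replicate 2, 166 without normal replicate 3, and 405, 311, 276 and 180 without high-methionine replicates 1, 2, 3 and 4; no named gene passed without normal replicate 2 or 3, and 1 passed without high replicate 4. After normexp background correction with an offset the differences were smaller, -0.54 for the KIF20A m6A ratio, -0.60 for the PRIM1 m6A ratio and -0.46 for the MOCOS m6A ratio, and all 3 still passed. With dim probes kept none of the 3 passed (adjusted p = 0.0960, 0.124 and 0.0985), at nearly the same differences (-1.18, -0.98 and -0.96). The split of higher and lower calls was 845 to 1229 after normexp background correction and 195 to 314 when scaled by spike-in probes. It was 19 to 17 with dim probes kept, and 321 to 314 for the percent in the IP channel, which was not centred.

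The next comparison concerned the amount of m6A-bound RNA, measured by the IP channel alone, which moves with both the m6A level and the abundance of a transcript. Of 46 named genes tested, 10 fell and 1 rose. ATAD2, a bromodomain ATPase, fell by 1.13 on the log2 scale (limma adjusted p = 0.0293), and NMI, an interferon-inducible partner of STAT proteins (-0.98, adjusted p = 0.0349), SPP1, the secreted macrophage product osteopontin (-0.74, adjusted p = 0.0320), and KIF20A (-0.80, adjusted p = 0.0209) fell too. ZAP70, a kinase of the T-cell receptor, rose by 0.81 (adjusted p = 0.0182). MOCOS, whose ratio fell, differed by 0.18 in the IP channel, which did not pass (adjusted p = 0.521). None of the 11 calls held without high-methionine replicate 3 or without high replicate 4; for the genes given here the adjusted p ran from 0.0508 for the ZAP70 m6A quantity to 0.106 for the NMI m6A quantity without the former, and from 0.0595 for ZAP70 to 0.0974 for the SPP1 m6A quantity without the latter. With dim probes kept 8 of the 11 were lost, and under spike-in scaling 7. Over 45102 probes 829 rose and 755 fell; scaled by spike-in probes 190 rose and 636 fell, and the slide as a block gave 6308 changed probes. The total of 1584 dropped to 750, 158 and 817 without normal-methionine replicates 1, 2 and 3, and to 424, 177 and 172 without high-methionine replicates 1, 3 and 4.

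The third comparison asked which transcripts differed in abundance, taken as IP plus Sup. ATAD2 was 2.15-fold less abundant in high methionine (log2 -1.10, SE 0.22, limma adjusted p = 0.0108, n = 4 per group). CD69, an early activation marker of leukocytes, fell by 1.00 (SE 0.25, adjusted p = 0.0233), a value that rests mainly on the IP channel because its Sup signal was not well above background on any array. Others that fell were PPIP5K2, an inositol pyrophosphate kinase (-0.91), ZZZ3, a subunit of a histone acetyltransferase complex (-0.91), RPAP3, a co-chaperone of RNA polymerase assembly (-0.91), NMI (-0.86), NOC3L, a nucleolar protein of ribosome assembly (-0.86), the kinetochore protein CENPQ (-0.79) and PLA2G4A, the cytosolic phospholipase that releases arachidonic acid (-0.78), with adjusted p between 0.0163 and 0.0243. The only named genes that rose were ZAP70 (2.73-fold, log2 1.45, SE 0.40, adjusted p = 0.0328) and MOCOS (1.76-fold, 0.81, SE 0.15, adjusted p = 0.00872), so MOCOS rose in abundance while its m6A ratio fell. The 4 arrays of each group did not overlap for any of these genes, which the rule for named genes required. In all, 25 of 46 named genes tested fell, 2 rose and 19 did not pass; adjusted over the list alone, 30 fell and 4 rose.

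**Figure D2:**
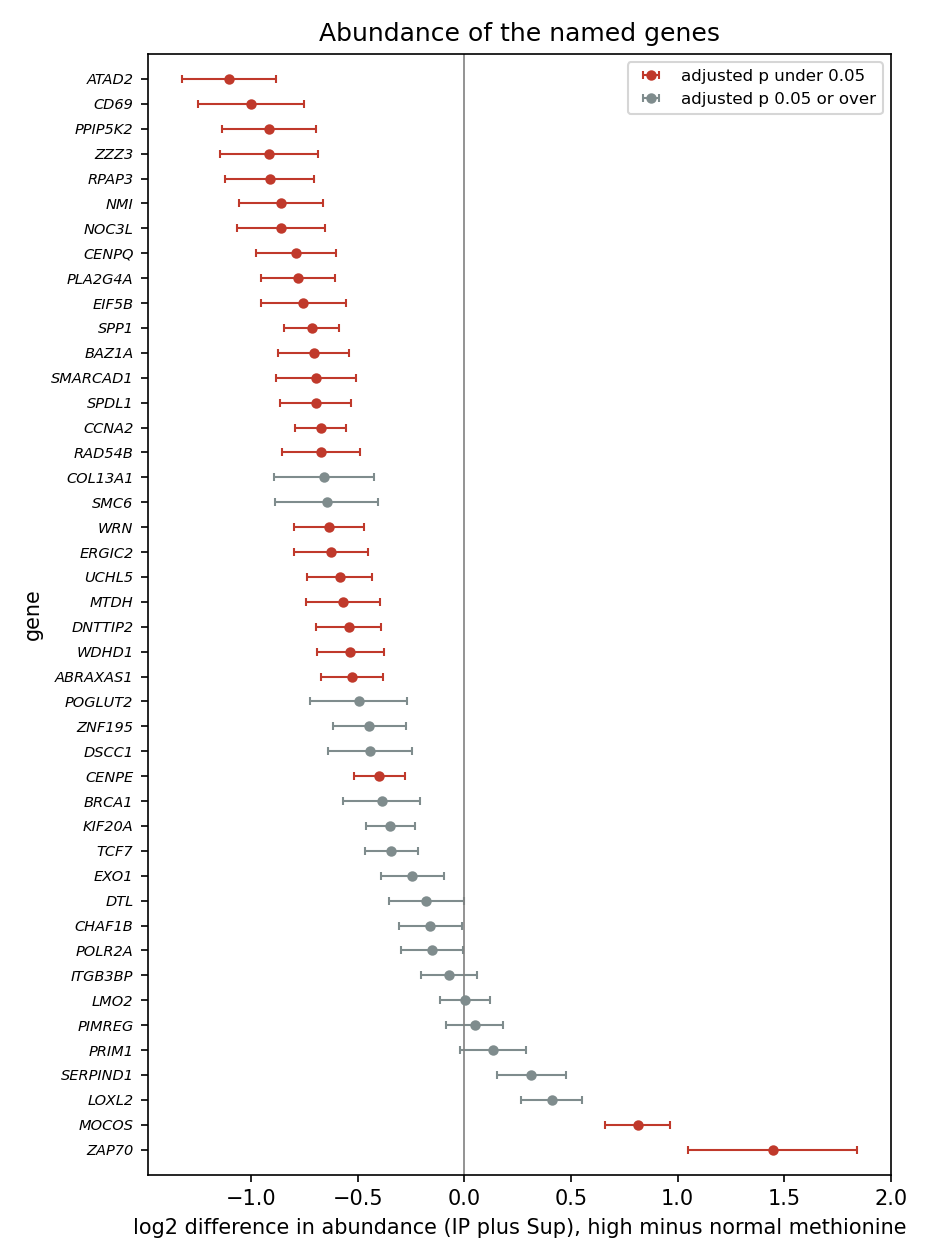
Log2 difference in abundance (IP plus Sup) between 4 arrays in high and 4 in normal methionine for 44 of the 46 named genes tested (points), with the standard error from limma (bars). Of the genes shown, ATAD2 lies at -1.10 and ZAP70 at 1.45; red points had an adjusted p under 0.05.

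Among the 9 genes of transcription, ribosome assembly and translation 7 fell and none rose, with a median of -0.75; besides ATAD2, ZZZ3, RPAP3 and NOC3L these were EIF5B (-0.75), BAZ1A (-0.71) and DNTTIP2 (-0.54), while POLR2A, the largest subunit of RNA polymerase II, differed by -0.15 (adjusted p = 0.492) and ZNF195 by -0.44 (adjusted p = 0.0958). Of 12 replication and repair genes 5 fell, namely SMARCAD1 (-0.70), RAD54B (-0.67), the helicase WRN (-0.63), WDHD1 (-0.53) and ABRAXAS1 (-0.53), and none rose. BRCA1 (-0.39, adjusted p = 0.159) and PRIM1 (0.13, adjusted p = 0.570) did not pass. Of 7 mitosis and kinetochore genes 4 fell: CENPQ, SPDL1, which recruits dynein to kinetochores (-0.70), cyclin A gene CCNA2 (-0.67, adjusted p = 0.00736) and CENPE (-0.40, adjusted p = 0.0455), whose sign turned after normexp (0.0378, adjusted p = 0.694 for CENPE abundance). The Sup signal of CENPE was well above background on 0 high and 1 normal array, and its IP channel did not pass (-0.28, adjusted p = 0.269). KIF20A differed by -0.35 (adjusted p = 0.0601). Of 8 immune and blood cell genes SPP1 (-0.72, SE 0.13, adjusted p = 0.00772), CD69, NMI and PLA2G4A fell and ZAP70 rose, while LMO2 differed by 0.00 (adjusted p = 0.981). Of the 6 remaining genes PPIP5K2, ERGIC2 (-0.62), UCHL5 (-0.58) and MTDH (-0.57) fell and MOCOS rose.

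These 5 groups were lower than other probes by camera, with adjusted p of 2.56e-05 for transcription and translation, 0.000514 for replication and repair, 0.00186 for mitosis, 0.0230 for the remaining genes and 0.0303 for immune and blood cell genes. None held with an estimated correlation (adjusted p = 0.292 for each). The fry test gave adjusted p of 0.0266, 0.0775, 0.0266, 0.0850 and 0.0455 for them. After normexp the group medians were smaller, -0.18 for replication and repair, -0.11 for mitosis and -0.11 for immune and blood cell genes, and for replication and repair the median was -0.31 without normal-methionine replicate 4. Within the named genes alone no group stood apart (adjusted p between 0.437 and 0.993). The call for immune and blood cell genes was lost in the Sup channel alone (adjusted p = 0.217), under spike-in scaling (0.116), after normexp (0.0506), with array weights (0.0639) and without high-methionine replicate 3 (0.0606); that for mitosis was lost in the Sup channel alone (0.0945) and that for the remaining genes under spike-in scaling (0.116) and in the Sup channel alone (0.0690). Of 4 matrix and adhesion genes 2 fell, SPP1 among them, while COL13A1 (-0.66, adjusted p = 0.0784) and LOXL2 (0.41, adjusted p = 0.0718) did not pass. The lymphocyte markers went both ways: ZAP70 rose, CD69 fell, and TCF7 (-0.34, adjusted p = 0.0804) did not pass. Of the liver and epithelial markers SERPIND1 was tested (0.31, adjusted p = 0.197); CPS1, SAA4 and CFTR were not well above background.

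Control probes for the glycolytic genes GAPDH and PGK1 were also lower in high methionine. The 3′ GAPDH probe averaged 6.15 ± 0.09 in high and 6.55 ± 0.07 in normal methionine (log2, scaled; SD, n = 4), a difference of -0.39 (exact two-sided permutation p = 0.0286, Benjamini-Hochberg adjusted 0.0571 over 8 tests). The 5′ GAPDH probe differed by -0.42, and the PGK1 probes by -0.30 at the 3′ end and -0.28 at the 5′ end, each with the same exact p, the smallest that 70 relabellings allow. All 4 differences stayed negative under median, quantile and spike-in scaling, in the Sup channel alone and on each slide. The distance between the 3′ and 5′ probes, a sign of RNA integrity, differed between groups by 0.02 for GAPDH (95% interval -0.19 to 0.23) and by -0.02 for PGK1 (-0.36 to 0.32).

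Over all 47551 probes tested for abundance 8576 changed, 5024 of them higher and 3552 lower, and 16546 had an unadjusted p under 0.05. The groups did not overlap for 12597 probes, 26.5% of those tested against 2.86% by chance. The largest rise under the rule was that of probe ASHG19AP1B10071231911 (5.08, SE 0.49, adjusted p = 0.000893), and the largest fall that of ASHG19AP1B12303246111 (-8.42, SE 0.37, adjusted p = 2.77e-05), which averaged 5.82 ± 0.92 in normal and -2.61 ± 0.16 in high methionine. With the slide as a block 12481 probes changed and 30 named genes fell; on slide 1 alone 6081 probes changed and 15 named genes fell, and of 6252 probes called there among those with a value on every array 5963 (95.4%) differed in the same direction on slide 2, against 76.1% of all probes. Normal-methionine replicate 4 had the highest median processed signal of the 8 arrays. Before dye normalization its median IP signal was 29.9, against 36.1 in high replicate 4. Without normal replicate 4, 7707 probes changed and 19 named genes fell. Scaling by spike-in probes moved the median of all probes from 0.05 to -0.13 and the split to 2091 higher and 5532 lower, and quantile normalization gave 3877 and 3921. The counts of changed probes and of named genes that fell dropped to 4742 and 14 without normal-methionine replicate 2, to 5630 and 10 without high replicate 1, and to 4538 and 5 without high replicate 3; without high replicate 4 they were 5687 and 19.

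The rise in ZAP70 abundance did not pass without 6 of the 8 arrays in turn (adjusted p from 0.0553 to 0.0813), these being normal replicates 2 and 3 and high replicates 1, 2, 3 and 4, nor under spike-in scaling (0.0655) or in the Sup channel alone (0.0639), and its Sup signal was above background on 2 of the 4 control arrays. Of the genes lower in abundance, PLA2G4A, CCNA2, CENPQ, CENPE, CD69, SMARCAD1, WRN, WDHD1 and RAD54B did not pass after normexp correction. The differences in ZAP70 abundance (0.54), MOCOS abundance (0.40) and ATAD2 abundance (-0.70) were smaller after normexp and still passed. In the Sup channel alone NMI, PPIP5K2, CD69, SMARCAD1, EIF5B, MTDH, WRN, ABRAXAS1, WDHD1, SPDL1, BAZ1A and DNTTIP2 did not pass.

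A last comparison asked whether the whole population of transcripts shifted towards the IP fraction. After calibration on the spike-in probes the median transcript had 55.8% ± 2.59 of its signal in the IP channel in high and 57.0% ± 3.06 in normal methionine (SD, n = 4), a difference of -1.25 percentage points that was smaller than the spread between arrays (exact two-sided permutation p = 0.486). Without calibration the difference was 1.69 (exact p = 0.429), and with spike-in probes above background on all 8 arrays 0.82 (exact p = 0.286), so its sign depended on the calibration. Within an array the log2 ratios of the 41 bright spike-in probes had an SD between 1.02 and 1.19, against 1.23 to 1.33 for transcript probes, although the labels state equal spike-in amounts in both fractions.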

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

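The tests of the slide and of the row in this part were chosen after the results were seen, and the split of the arrays was planned. Among 182 sets of 4 arrays checked for an array far from the other 3 of its group, 18 were singled out, where chance, at about 1 in 20, gives 9.1. Normal-methionine replicate 4 accounted for 12 of them. It lay above the other control arrays in abundance for CCNA2 (-1.43, others -1.76 to -1.72), CENPQ (-1.42, others -2.13 to -2.05), DSCC1 (-0.0165), DTL (-0.257), ERGIC2 (0.857), NMI (4.01, others 3.22 to 3.34), NOC3L (1.89, others 0.999 to 1.12), SPDL1 (-0.166), UCHL5 (0.964) and WDHD1 (-1.82), and below them for SERPIND1 (-1.64). Its ABRAXAS1 m6A ratio (-0.0604) lay above the others (-0.846 to -0.719).

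High-methionine replicate 3 accounted for 4, among them a lower abundance than the other high-methionine arrays of NOC3L (0.0825, others 0.476 to 0.553), SMARCAD1 (-2.01) and ZZZ3 (-0.667, others -0.262 to -0.196). In high replicate 1 the CHAF1B m6A ratio (1.81, others 1.19 to 1.24) stood apart, and in high replicate 4 the abundance of ITGB3BP (-3.11, others -3.39 to -3.35).

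Control probes outside the transcript set were higher in high methionine on all 4 arrays: ERCC probes by 0.365, ETG probes by 0.249 and ASSPINKEIN probes by 0.176 on the log2 scale (exact permutation p = 0.0286 each, adjusted 0.0571 over 6 classes). The ERCC probes averaged -5.07 and -5.44 in the groups, and the negative controls, which differed by 0.16 (exact p = 0.200), averaged -6.16 and -6.33. The bright CUST probes went the other way (-0.22, exact p = 0.0857), as did the GAPDH and PGK1 control probes (-0.28 to -0.42), and E1A probes were higher by 0.26 (exact p = 0.0571).

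The number of probes that changed in abundance, 8576, was reached by 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, and the highest other split gave 0, which argues against chance; 1 of 35 is the smallest share these splits can give. Each slide held as many normal as high arrays, so a constant difference between the slides could not by itself make a group difference. On slide 1 alone 6081 probes changed. The row of the arrays on the slide cannot be told apart from methionine, because 0 arrays of either group lay in the other group's row. An effect of methionine and one of array position therefore both stay open for the m6A ratio, the m6A quantity, abundance and control-probe differences.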

How the results depend on the processing

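Slide 1 alone and the counts of named genes were examined after the data were seen; the other settings were planned. Of 757 probes with a changed m6A ratio in the chosen setting, the count became 2074 after normexp, 1576 with loess added, 36 with dim probes kept (60541 tested), 1955 with the slide as a block, 1769 with array weights, 2842 at an unadjusted p with a 1.5-fold change and 217 on slide 1 alone (6 arrays); leaving out arrays gave 160 to 782. The 3 named genes with a lower ratio became 9, 7, 0, 5 and 0 with normexp, loess, dim probes, the slide block and slide 1, and 0 to 3 with an array left out. No called probe changed sign in any of these fits.

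For the m6A quantity 1584 became 826 scaled by spike-in probes, 471 with dim probes kept, 6308 with the slide block, 4948 with array weights and 4317 at an unadjusted p; leaving out arrays gave 158 to 1783. For abundance 8576 stayed within 1.5 times in all settings but 4 left-out arrays (4538 to 7707 over all 8). The 25 named genes with a lower abundance became 16 after normexp, 15 in the Sup channel and 15 on slide 1, and 5 to 23 with an array left out; the 2 that rose became 4 with the slide block and with array weights. Of named genes not called for the m6A quantity in the chosen setting, 17 were called with the slide block, 15 with array weights, 14 at an unadjusted p and 7 with the trended prior; the replicate block lost 7 of the 11 calls. CENPE abundance turned from -0.40 to 0.0378 after normexp (adjusted p = 0.694; adjusted p between 0.0130 and 0.125 in its other fits that adjust over probes), and 110 and 31 of the 8576 called probes changed sign with normexp and Sup alone. Slide 1 alone had fewer arrays, which may lower counts, but for the m6A quantity it gave 1731 changed probes, above the 1584 of the chosen setting. The cause of these differences between settings was not tested. The IP share after calibration stayed between -2.75 and -0.12 percentage points with arrays left out.

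The replicate number as a block gave 146 probes and 0 named genes for the ratio (KIF20A, PRIM1 and MOCOS kept their differences, with adjusted p = 0.0516, 0.0787 and 0.0783), 657 probes for the quantity and 7325 for abundance. Same-numbered arrays did not deviate together (r from -0.33 to 0.15 for the ratio), so the numbers were not taken as pairs. The tests of fixed gene lists were not run, since no list had 5 tested genes. Signal over background limits the ratio: 6 of the 50 named genes could not be tested for it.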

Other observations

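Of the tests in this part, those of RNA degradation, dim probes, the second slide, the share of lower calls without dye normalization and the named genes with arrays as the unit were chosen after the results were seen. Across probes, abundance differences followed the IP over Sup ratio. No dyes were swapped, so this ratio was not shown to rank probes by m6A level. Among the tenth of probes with the lowest IP over Sup ratio 29.7% rose and 8.62% fell in abundance (median 0.25), and among the tenth with the highest ratio 0.988% rose and 20.5% fell (median -0.33). Probes are not independent replicates, and ratio and abundance come from the same signals, so they are not independent measures.

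Of 543 probes with a lower m6A ratio 342 had a higher abundance, where independent lists would share 54.7, and 16 a lower one, where they would share 40.7. Of 214 with a higher ratio 113 had a lower abundance, against 16.0. Both measures come from the same 2 signals, and a change in Sup alone moves them in opposite directions. Part of this excess is therefore built in, and independence is not the proper expectation. Over 10 equal bins of signal, the first 8 from the dimmest up each had more lower than higher ratio calls (53 and 18 in the first, 60 and 27 in the eighth), while the ninth had 21 and 25 and the brightest 4 and 35. MOCOS was the named gene with a lower ratio and a higher abundance, and its IP channel did not pass (0.18, limma adjusted p = 0.521). Across probes the 2 differences had Pearson's r of -0.45 and Spearman's rho of -0.36. By ID class, the median abundance of ASHG38SM probes differed by 0.19 and that of ASHGV4 probes by 0.13 (exact permutation p = 0.0286 each, adjusted 0.0952 over 10 tests, higher on all 4 high-methionine arrays); what these classes stand for is not given in the sources used here.

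For the named genes, mostly lower in high methionine (median -0.56 over 46), random probe sets matched on abundance and m6A ratio had a median of -0.16, and at most 0.01% of 10000, the smallest share they can give, were as low; such sets ignore the correlation between the named genes, estimated at 0.534, with which camera did not call them lower than other probes (p = 0.186). With arrays as the unit the genes were lower than matched probes by 0.32 (95% interval of the difference -0.48 to -0.17), which argues against the relation with the ratio as the whole cause. In the Sup channel alone the genes' median was -0.42 (95% interval over genes -0.52 to -0.32), but the planned bound of -0.1 ignored their correlation and the interval over arrays (-0.75 to -0.04) reaches past it, so unequal scaling of the fractions cannot be told apart. The GAPDH 3′ minus 5′ difference of 0.0232, with an interval that excludes 0.28, argues against RNA degradation, although the interval for PGK1 does not exclude it. A lower expression of these genes in high methionine may be the source, as a hypothesis, but they share a probe design that no other transcript probe has, and array position stays open.

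More probes had a lower than a higher m6A ratio, and the number changed, 757, was reached by 1 of 35 splits (the real one; highest other 2), as was the 1584 for m6A quantity (1 of 35, highest other 0), which argues against chance for both. Array position stays open for both, because all high arrays share a row. After normexp and loess 73.2% of 1576 calls were lower, but loess is itself a dye normalization. With normexp and no such step the share was 59.3% (57.1% to 61.4%), which spans the bound of 60%, so a part played by the dye normalization cannot be told apart. An excess of lower calls remained without that step, with 1229 lower and 845 higher. On slide 1 alone the share of lower calls was 63.6% (with a 95% interval whose lower end, 56.8%, lies below the bound of 60%), so that bound did not decide on the second slide. The excess remained there without slide 2, with 138 lower and 79 higher calls. With the slide as a block 1272 were lower and 683 higher. Each slide held as many normal as high arrays, so the block hardly moved the differences themselves and could not decide on the second slide. Among the brighter probes 211 of 329 calls were lower (64.1%, exact binomial 95% interval 58.7% to 69.3%), so a part played by dim probes cannot be told apart. In the seventh of 10 bins from the dimmest up 63 were lower and 13 higher. The ninth had 21 and 25, and in the brightest the excess was reversed (4 and 35). All intervals in this paragraph treat probes as independent, which they are not, and ignore the spread between arrays, so they may be too narrow. The excess was absent for the percent in the IP channel (49.4% lower). That fit used another scale and was also not centred, with a median difference of 0.98 percentage points over all probes. The scale and the missing centring cannot be told apart.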
